A study of Mus musculus with 12 samples.

How the data were processed

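Whole-brain poly(A) RNA was measured in 12 mouse libraries, 3 in each of the 4 combinations of genotype (WT, CCR2-DTR) and infection (naive, 8 days after infection). Per the labels' protocols, RNA was extracted with TRIzol, samples with an RNA integrity number above 7 were kept, poly(A) RNA was selected in 2 rounds, and libraries were made with a NEBNext Ultra kit for Illumina sequencing. The deposited values are raw counts per gene, named total counts per the file headers, in 1 table of 53715 genes with symbols, Ensembl identifiers and coordinates. The genome build is GRCm38, per the submitters' processing notes. The aligner, the counting program and its strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes may share reads. Of the identifiers, 53620 are in GENCODE M21, and 52056 have the same coordinates there. No count was recorded in any library for 24450 genes. 

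Replicates of a group were checked for duplicates. Their log2 CPM correlated with Pearson r between 0.990 and 0.994, and a chi-square test of the counts gave between 8.20 and 30.3 per degree of freedom, so all 12 were kept as separate samples. The depth was 41149309 to 64666080 counts per library, so that 1 CPM is 41.1 to 64.7 counts before scaling. CPM values, computed here from the deposited counts with TMM-scaled library sizes, are given as mean ± SD.

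Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (19372) were scaled by TMM and fitted with robust quasi-likelihood models over all 12 libraries and 4 groups, so that the groups share one estimate of the spread. The 5 contrasts were infection within each genotype, genotype within each infection state, and their interaction. Log2 fold changes are given ± SE, and a gene was said to change when its Benjamini-Hochberg adjusted p was under 0.05. Lists of genes for cell types, brain regions and pathways, 41 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated per list. The design, the lists, the alternative settings other than the 5 named last and the rule for named genes were fixed before the data were examined. The rule named Ccr2, Hbegf and sex-linked genes, the 10 largest rises and falls per contrast among changed genes with a mean of at least 1 CPM and no overlap between replicates (the 5 smallest p where fewer than 5 passed), and, for lists, the 4 members with the smallest p and any changed member. Predicted genes were left out. Groups of 3 against 3 do not overlap by chance for 10% of genes.

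The gene test was checked on counts simulated from these libraries with 200 of 19372 genes changed. For infection in WT it called 64.2%, 74.6% and 100% of genes changed by 0.5, 1 and 2 log2 units. The shares were 61.2%, 76.1% and 98.5% for infection in CCR2-DTR, 67.2%, 71.6% and 100% for genotype in naive, 59.7%, 80.6% and 97.0% for genotype in infected, and 26.9%, 68.7% and 93.9% for the interaction with the change in infected CCR2-DTR libraries. Contrasts without a simulated change called at most 1 gene, and those with one called 3 to 13 unchanged genes. Counts were drawn independently for each gene from its fitted spread. Variation shared between genes was not simulated, so these rates may not hold in the real libraries.

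The alternative settings were 2 other scalings, no filter and a stricter filter (CPM of at least 1 in 6 libraries), DESeq2 1.42.0, limma voom with quality weights, a fit of the compared groups only, the replicate number as a block, the suffix of the sample code as a covariate (CS169 in WT naive replicate 3, WT infected replicate 1 and CCR2-DTR naive replicate 3, and CS167 in the other 9 libraries, among them all of infected CCR2-DTR), and leaving out each library. Fits on fewer libraries kept the 19372 genes. Sex as a covariate was not run because the sex-linked genes had the same pattern in all 12 libraries. Fits added after the data had been seen were mitochondrially encoded genes left out, a correction for GC content and length (values for 99.8% of genes, from GENCODE M21), the CS167 libraries only, the olfactory bulb score as a covariate, and the 2 CCR2-DTR naive libraries with the highest score left out. The last of these fits had 1 library in the naive CCR2-DTR group. The result of 1 further test is not reported here.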

Results

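Poly(A) RNA of the whole brain was sequenced in adult C57BL/6 mice of 8 to 12 weeks. Wild-type (WT) mice were compared with CCR2-DTR mice, a line in which cells that express the chemokine receptor Ccr2, such as classical monocytes, carry the diphtheria toxin receptor and can be depleted. Mice of each genotype were either naive or had been infected for 8 days with Trichinella spiralis, a parasitic nematode that settles in gut and muscle. The 4 groups held 3 libraries each. The total was between 41149309 and 64666080 counts per library. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. They also do not say whether the WT mice or the naive CCR2-DTR mice received toxin. An effect of toxin therefore cannot be told apart from genotype. If only the infected CCR2-DTR mice received toxin, its effect also cannot be told apart from that of infection in CCR2-DTR mice or from the interaction.

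The genes named by the depletion model were examined first. Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557, GRCm38) was low in naive WT brains, at 0.223, 0.402 and 0.280 CPM (counts scaled to library size). It was at 3.33, 2.38 and 2.68 CPM in infected WT brains, a rise that missed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.087). In infected CCR2-DTR brains it was at 0.475, 0.201 and 0.523 CPM. In naive CCR2-DTR brains 2 libraries were at 0.392 and 0.177 CPM and replicate 1 was at 4.17 CPM (227 counts), above every other library. The log2 difference in Ccr2 between infected genotypes was -2.78 ± 0.99 (SE, n = 3 per group) and did not pass either (edgeR adjusted p = 0.34). Both tests used a spread shared by all 12 libraries, among them the naive CCR2-DTR libraries, which ranged from 0.177 to 4.17 CPM. In neither comparison did the replicates of the 2 groups overlap. That held for 29.5% of all tested genes for infection in WT and for 20.2% between infected genotypes. The 2 misses do not show that Ccr2 was unchanged. Hbegf, the mouse counterpart of the gene that encodes the diphtheria toxin receptor, was between 16.8 and 20.0 CPM in all 12 libraries. In all 12 libraries Xist had between 24831 and 39171 counts and the Y-linked genes Ddx3y at most 2, Uty at most 4, Eif2s3y at most 1 and Kdm5d 8 to 24. Xist was lower in naive CCR2-DTR than in naive WT brains (-0.41 ± 0.09, SE, edgeR adjusted p = 0.031).

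The first question was what infection did in the brain of WT mice. Genes of activated glia, immune cells and cell division were higher in infected WT brains. Of 19372 genes tested, 2556 changed (edgeR, adjusted p under 0.05), 1569 higher and 987 lower, and 546 changed more than 2-fold, of which 539 were higher. With upper-quartile scaling the split was 1818 higher and 656 lower, and with a correction for GC content and length, added after the data had been seen, it was 1430 higher and 1398 lower. Hmox1, the heme-degrading enzyme, rose from 2.84 ± 0.0309 to 40.7 ± 4.16 CPM (SD, n = 3), a log2 fold change of 3.84 ± 0.14 (SE, edgeR adjusted p = 9.8e-09). Here and below, the largest rises and falls are those among changed genes with a mean of at least 1 CPM and no overlap between replicates, with predicted genes left out. The largest rises were in Lcn2 (lipocalin 2, 4.94 ± 0.75), Tgm1 (4.80 ± 0.42), Lilr4b (16.0-fold), the mitotic genes Cdk1 (3.92 ± 0.49) and Top2a (3.88 ± 0.58), Chil3 (3.88 ± 0.47), the chemokine Ccl12 (3.84 ± 0.54), Cst7 (3.60 ± 0.55) and Timp1 (3.57 ± 0.25). The largest falls were smaller, in Egr2 (-0.84 ± 0.24), Rpe65 (-0.84 ± 0.25), Homer1 (-0.78 ± 0.13), Noxred1 (-0.78 ± 0.16), Zbtb9 (-0.75 ± 0.15), Egr1 (-0.71 ± 0.17), Vgll3 (-0.70 ± 0.18), Nr4a3 (-0.68 ± 0.10), Gucy2g (-0.64 ± 0.14) and Fam198b (-0.63 ± 0.16). Rpe65 kept its call in 15 of 26 alternatives (-0.44 without WT naive replicate 3) and Egr2 in 16 of 26, and both lost it without any 1 of the WT infected replicates.

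**Figure D1:**
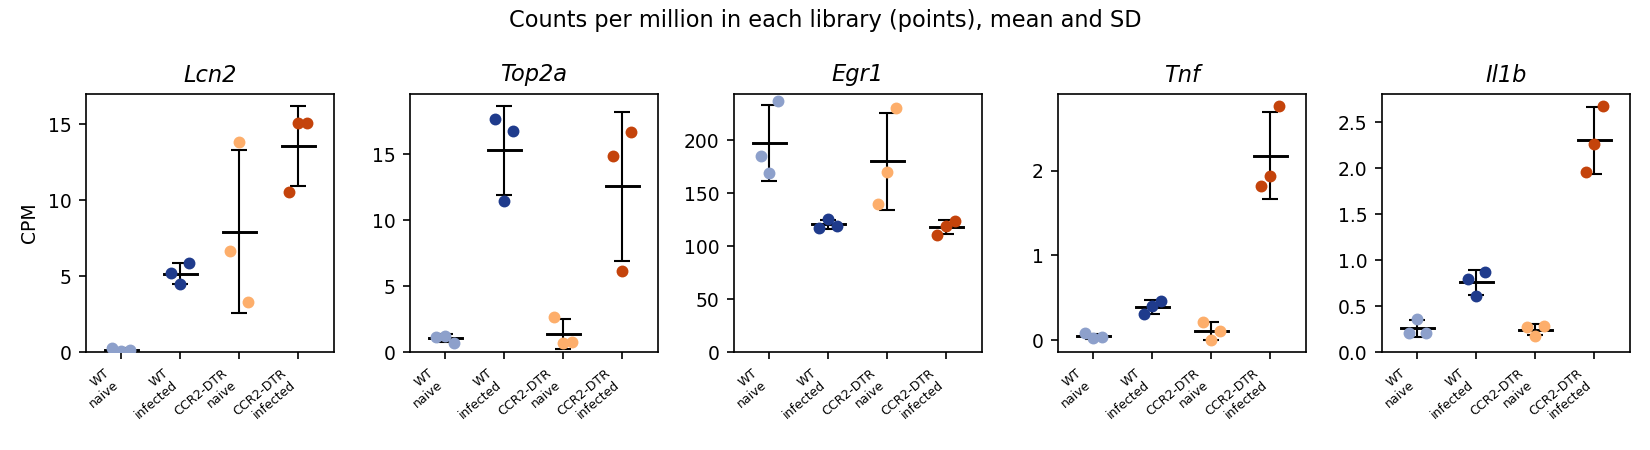
CPM (linear axes) of Lcn2, Top2a, Egr1, Tnf and Il1b in each of the 12 libraries, with points for libraries, horizontal lines for group means and bars for SD (n = 3). Egr1 lay at 120.6 ± 4.42 CPM in infected and 197.5 ± 35.7 CPM in naive WT brains.

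Glial and immune gene lists rose in infected WT brains. Of the reactive astrocyte list 14 of 17 tested members rose (15 adjusted over the list alone, as is each second count given below for a list), among them the intermediate filament genes Gfap (2.73 ± 0.25) and Vim (1.29 ± 0.12), with Serpina3n (2.70 ± 0.26) and Aspg (1.79 ± 0.12). Of the disease-associated microglia list 16 of 18 rose (16 over the list alone), with Clec7a at 3.33, Itgax at 3.16 and Lgals3 at 3.03. Homeostatic microglia genes moved the same way, with 15 of 18 higher (16 over the list alone) and a median log2 fold change of 0.78, as in Trem2 (0.94 ± 0.09) and Cx3cr1 (0.79 ± 0.09). Complement genes rose in 13 of 14 (13 over the list alone), including C1qb (1.33 ± 0.11), C3 (2.30 ± 0.29) and C4b (2.06 ± 0.20). All 16 proliferation genes rose, with a median of 2.59, among them Mcm3 (1.44 ± 0.15), a DNA replication helicase subunit. In the antigen presentation list 14 of 16 rose (16 over the list alone). The MHC class II genes H2-Ab1 (2.39 ± 0.13), H2-Aa (2.11 ± 0.18) and H2-Eb1 (2.00 ± 0.20) and the invariant chain gene Cd74 (2.46 ± 0.13) led it. Classical monocyte genes rose in 11 of 15 (12 over the list alone), as in Lyz2 (1.94 ± 0.14) and Plac8 (2.94 ± 0.36).

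Cytokine genes and type 2 immune genes also rose. Of the NF-kB and cytokine list 15 of 24 were higher and 1 was lower (18 and 1 over the list alone), with Ccl2 at 5.44 ± 0.62 and Il1a at 2.13 ± 0.22. Of the type 2 immunity list, which covers responses typical of worm infection, 9 of 15 rose (11 over the list alone, with 1 lower), led by Retnla (5.73 ± 0.37), Ccl24 (3.84 ± 0.41) and Arg1 (3.23 ± 0.44). The type 2 list kept its call in 25 of 26 alternatives (highest camera adjusted p = 0.086). Its median was 1.37, between 1.25 and 1.38 with 1 library left out, and 0.072 at the lowest among all alternatives. Retnla, Ccl24 and Ccl2 are not among the largest rises given above. They missed at least 1 of the bounds set there, a mean of at least 1 CPM and no overlap between replicates. Low counts may therefore limit these values. Border-associated macrophage genes rose in 9 of 13 (10 over the list alone), as in Mrc1 (1.03 ± 0.12), and general astrocyte genes in 7 of 15 (7 over the list alone) by smaller amounts, as in Aldh1l1 (0.45 ± 0.07) and Aqp4 (0.34 ± 0.07). The set test (camera, preset correlation) called 23 of 41 lists. With a correlation estimated for each list it called 12, all higher, which are the 11 lists described so far in WT mice and the endothelial activation list (9 of 18 genes higher, 13 over the list alone). The interferon list lost its call (7 of 26 higher, 15 over the list alone, as in Ifitm3 at 1.44 ± 0.22 and Gbp2 at 1.76 ± 0.36, adjusted p = 0.30 with an estimated correlation). The immediate early gene list did too (6 of 17 lower, 7 over the list alone, adjusted p = 0.36 with an estimated correlation). Without WT infected replicate 1, which had the highest mitochondrial share (18.8%), 1281 genes changed, 237 of them lower, and without WT naive replicate 2 the number was 1584, with 447 lower.

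The same comparison in CCR2-DTR mice asked what infection did where monocytes could be depleted. Genes of activated glia, cytokines and cell division were higher in infected CCR2-DTR brains. Between infected and naive CCR2-DTR brains 1337 genes differed, 1083 higher and 254 lower with infection (edgeR, adjusted p under 0.05). With the GC and length correction the split was 1107 higher and 729 lower. The largest rises were in Tgm1 (4.45 ± 0.38), the cytokine gene Tnf (4.32 ± 0.47), Il1rn (4.01 ± 0.47), Bcl2a1a (3.66 ± 0.29), Hmox1 (3.60 ± 0.14), Ptx3 (3.55 ± 0.32), Ccl2 (3.29 ± 0.40), Il1b (3.24 ± 0.25), Hcar2 (3.21 ± 0.34) and Top2a (3.20 ± 0.55). Bcl2a1a belongs to a family of near-identical gene copies, so its count is uncertain. Reactive astrocyte genes rose in 13 of 17 (15 over the list alone, Gfap 2.22 ± 0.24), NF-kB and cytokine genes in 16 of 24 (20, Il1a 2.96 ± 0.20, Cxcl2 3.90 ± 0.45), disease-associated microglia genes in 15 of 18 (16, Lgals3 2.04 ± 0.19), homeostatic microglia genes in 12 of 18 (13, Trem2 0.73 ± 0.08), complement genes in 9 of 14 (11, C1qb 1.07 ± 0.11), type 2 genes in 8 of 15 (9, Retnla 3.78 ± 0.37) and proliferation genes in 16 of 16 (16, Mcm3 1.55 ± 0.14). Of 23 lists called with the preset correlation, 11 held with an estimated one, among them all 7 named in the last sentence. Cxcl2 and Retnla missed at least 1 of the bounds for the largest rises. Antigen presentation genes rose in 5 of 16 (9 over the list alone), including Cd74 (1.33 ± 0.13), and the list was no longer called with an estimated correlation (adjusted p = 0.21 with an estimated correlation). The same held for classical monocyte genes, of which 6 of 15 rose (8 over the list alone), as in Lyz2 (1.17 ± 0.14, adjusted p of the list = 0.18 with an estimated correlation).

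The largest falls in infected CCR2-DTR brains were in Ms4a15 (-5.11 ± 1.04), Frmd7 (-3.04 ± 0.61), Eomes (-2.68 ± 0.62), Shisa3 (-2.50 ± 0.53), Cdhr1 (-2.01 ± 0.41), Cpa6 (-1.66 ± 0.39), Sp8 (-1.57 ± 0.32), Lgr5 (-1.34 ± 0.35), Otop2 (-1.07 ± 0.28) and Shisa8 (-1.07 ± 0.23). Lgr5 passed narrowly (edgeR adjusted p = 0.0499) and kept its call in 4 of 26 alternatives. The other 9 kept theirs in 11 of 25 (Eomes) to 20 of 26 (Sp8). Without naive CCR2-DTR replicate 1 the values of Lgr5 and Otop2 were -0.88 and -0.71. None of the 10 was called with the olfactory bulb score described below as a covariate. Eomes, Shisa3 and Cdhr1 are in the olfactory bulb list and so in the score, so their lost calls with it are no independent test. Of this list 4 of 10 fell (8 over the list alone, camera adjusted p = 0.12 with an estimated correlation). Inhibitory neuron genes fell in 4 of 14, namely Gad1, Dlx1, Dlx2 and Calb2 (7 over the list alone, adjusted p = 0.016 with an estimated correlation). With the score as a covariate none of these 4 was called, at -0.41 for Gad1, -0.11 for Dlx1, -0.13 for Dlx2 and -0.14 for Calb2, against -0.54, -0.58, -0.63 and -0.60 without it. The inhibitory neuron list as a whole kept its call in all 26 alternatives, with medians between -0.23 and -0.16. Its fit with the score used the preset correlation. The olfactory bulb score is the mean log2 CPM of the olfactory bulb list. It was 3.48 and 3.09 in naive CCR2-DTR replicates 1 and 3, 2.04 in replicate 2 and between 1.43 and 2.00 in the other 9 libraries. Without both high libraries 666 genes changed, 26 of them lower. With the score as a covariate 296 changed, 6 of them lower. Both fits were added after the data had been seen. Without replicate 3 of either CCR2-DTR group the number was 870 (naive, 85 lower) or 749 (infected, 65 lower).

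The infection effects in the 2 genotypes were set side by side, since they share no library. Across 19372 genes, which are not independent replicates, their log2 fold changes correlated with Pearson r = 0.624. The r was 0.148 with no low-count filter, 0.196 with DESeq2 and 0.858 with the stricter filter. Of all 19372 genes 75.6% had the same sign in both genotypes. Of 2817 genes that changed in either genotype, which were selected by these calls, 2759 had the same sign in both. Changes in both genotypes were found for 1076 genes, 936 higher and 140 lower, where independent lists would share 87.7 and 12.9. None of the 1076 had opposite signs.

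**Figure D2:**
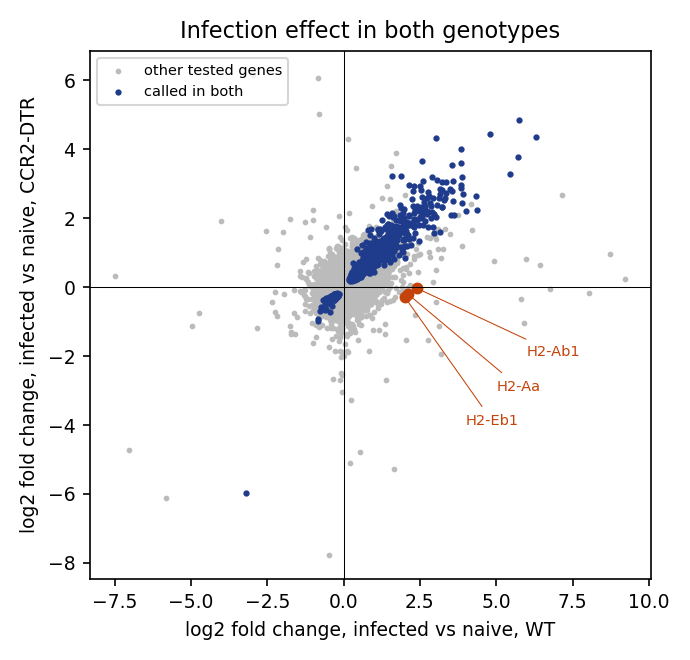
Log2 fold change of infected against naive brains in WT (horizontal) and CCR2-DTR mice (vertical), 1 point per tested gene (19372), with the 1076 genes changed in both in blue. H2-Ab1, H2-Aa and H2-Eb1, in orange, lie near 2.39, 2.11 and 2.00 on the WT axis and near 0 on the CCR2-DTR axis.

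In naive mice the genotypes differed most clearly in Ccr3 and Tsc22d2. Ccr3, a chemokine receptor gene close to Ccr2 (ENSMUSG00000035448, chromosome 9, 124021972 to 124031689, GRCm38), was at 5.85 ± 0.643 CPM in naive CCR2-DTR brains and 0.0753 ± 0.0630 CPM in naive WT brains (SD, n = 3; between 2 and 7 counts per WT library), with edgeR adjusted p = 5.0e-09. Tsc22d2 was at 18.0 ± 0.630 and 33.6 ± 0.831 CPM, a log2 difference of -0.90 ± 0.06 (SE, edgeR adjusted p = 1.0e-06). Both calls held under all 26 alternatives tried. In all, 658 genes differed, 254 higher and 404 lower in CCR2-DTR mice. This number was not stable. It was 1709 with DESeq2, 1414 with the replicate number as a block and 1031 with the sample code suffix as a covariate. It was 9 when only these 6 libraries were fitted, 25 after a correction for GC content and length, 6 with the olfactory bulb score as a covariate and 44 without naive CCR2-DTR replicates 1 and 3, the last 3 added after the data had been seen. It was 21, 104, 172 and 417 without WT naive replicates 1 and 2 and CCR2-DTR naive replicates 1 and 3. By direction, it was 2 higher and 7 lower with only these 6 libraries and 8 higher and 17 lower after the GC and length correction. With the olfactory bulb score it was 5 higher and 1 lower. Without CCR2-DTR naive replicate 2 it was 107 higher and 60 lower, and without replicate 3 it was 211 higher and 206 lower. It was 386, 438 and 364 without WT infected replicate 1 and CCR2-DTR infected replicates 2 and 3.

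Among the other genes that differed between naive genotypes, the largest differences towards CCR2-DTR were in Ms4a15 (5.93 ± 1.19), Lcn2 (5.56 ± 0.72), Frmd7 (3.14 ± 0.63), Eomes (3.05 ± 0.65), Ch25h (2.42 ± 0.41), Shisa3 (2.37 ± 0.54), Cdhr1 (2.13 ± 0.41), Ppm1j (1.85 ± 0.42) and Sp8 (1.54 ± 0.32). Of these 9, the calls other than those of Lcn2 and Ch25h were lost both with the olfactory bulb score as a covariate and without naive CCR2-DTR replicates 1 and 3. Eomes, Shisa3 and Cdhr1 are part of that score, so their losses with it are no independent test. The fit without replicates 1 and 3 had 1 library in its group. Of the olfactory bulb list 6 of 10 were higher (9 adjusted over the list alone, camera adjusted p = 0.11 with an estimated correlation). Eomes was at 5.87, 0.733 and 4.32 CPM in naive CCR2-DTR replicates 1, 2 and 3 and at most 0.578 CPM in naive WT brains. Lower were Olfr648 (-1.02 ± 0.22), Kcne2 (1.57 against 3.15 CPM), Prlr (-0.98 ± 0.15), Calml4 (-0.89 ± 0.15), Tmem72 (-0.85 ± 0.14), Kcnj13 (-0.85 ± 0.21), Ugt8a (-0.76 ± 0.15), Sorbs2os (-0.71 ± 0.16) and Fsbp (-0.70 ± 0.17). These 9 calls were kept in 12 of 26 (Kcnj13) to 22 of 26 alternatives (Calml4) and lost with the olfactory bulb score as a covariate. Over all alternatives their weakest values ran from -0.85 (Olfr648) to -0.43 (Prlr). With the score the median SE of the called genes outside the olfactory bulb list rose from 0.072 to 0.13. The lost calls therefore do not show an olfactory bulb origin of these genes. Of the choroid plexus list 5 of 17 were lower (10 lower and 1 higher over the list alone, adjusted p = 0.28 with an estimated correlation). Of the endothelial activation list 3 of 18 were higher (13 over the list alone), among them the adhesion gene Icam1 (1.29 ± 0.22, adjusted p of the list = 0.14 with an estimated correlation). Of the NF-kB and cytokine list 3 of 24 were higher (8 over the list alone), namely Icam1, Ccl2 (3.20 ± 0.77) and Cxcl1 (1.83 ± 0.42), and 21 of 24 values were positive, with a median of 0.68 (adjusted p of the list = 0.28 with an estimated correlation). The median was 0.078 with the olfactory bulb score as a covariate and 0.22 without CCR2-DTR naive replicate 1. The call of Ccl2 was kept in 10 of 26 alternatives and that of Cxcl1 in 16 of 24. Cholesterol synthesis genes were lower in 5 of 16 (6 over the list alone), as in Idi1 (-0.59 ± 0.08) and Hmgcs1 (-0.50 ± 0.08, adjusted p of the list = 0.35 with an estimated correlation). The preset correlation called 19 lists and the estimated correlation 0 (6 at an unadjusted p under 0.05). Mitochondrially encoded genes took 11.7% ± 1.36 of counts in naive CCR2-DTR and 14.3% ± 0.534 in naive WT libraries (SD, n = 3).

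**Figure D3:**
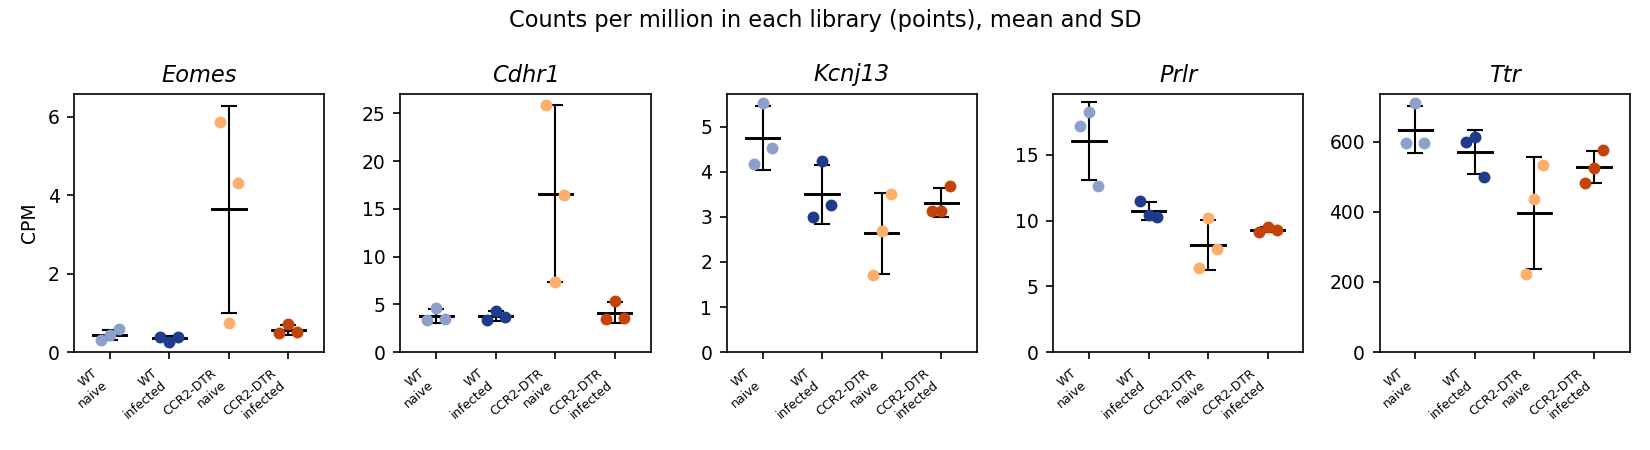
CPM (linear axes) of the olfactory bulb genes Eomes and Cdhr1 and the choroid plexus genes Kcnj13, Prlr and Ttr in each of the 12 libraries, with points for libraries, horizontal lines for group means and bars for SD (n = 3). Prlr lay at 8.13 ± 1.92 CPM in naive CCR2-DTR and 16.0 ± 2.97 CPM in naive WT brains.

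In infected mice the genotypes differed in MHC class II and inflammatory cytokine genes. H2-Aa (-2.94 ± 0.19), H2-Eb1 (-2.78 ± 0.21), H2-Ab1 (-2.59 ± 0.14) and Cd74 (-1.29 ± 0.12) were lower in CCR2-DTR brains. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34263209 to 34269418, GRCm38) was at 1.57 ± 0.0884 against 9.45 ± 0.588 CPM (SD, n = 3; edgeR adjusted p = 6.6e-08). Also lower were Chil3 (-2.32 ± 0.39), Retnla (-1.47 ± 0.23), Tsc22d2 (-0.74 ± 0.06), Lpar1 (-0.40 ± 0.07) and the cholesterol synthesis genes Idi1 (-0.53 ± 0.08) and Hmgcs1 (-0.45 ± 0.08). Higher were Ccr3 (5.20 ± 0.239 against 0.0675 ± 0.0239 CPM), Tnf (2.45 ± 0.39), Cd40 (1.83 ± 0.21), Hcar2 (1.62 ± 0.30), Il1b (1.60 ± 0.22), Il1a (1.25 ± 0.18), Icam1 (1.19 ± 0.20) and the NF-kB regulators Tnfaip3 (1.11 ± 0.12), Nfkbie (0.99 ± 0.14) and Bcl3 (0.94 ± 0.18). The calls of Icam1 (kept in 13 of 26 alternatives), Bcl3 (15 of 26) and Hcar2 (14 of 25) were lost without any 1 of the WT infected replicates and without CCR2-DTR infected replicate 2 or 3. Tnf kept its call in 17 of 25, Chil3 in 18 of 25, Retnla in 20 of 25, Hmgcs1 in 18 of 26, Lpar1 in 19 of 26, Idi1 in 20 of 26 and Il1a in 22 of 26, and all 7 lost it without WT infected replicate 1 or 3. Of the NF-kB and cytokine list 6 of 24 were higher (16 over the list alone), and it was called with an estimated correlation (adjusted p = 0.022 with an estimated correlation). Its median was 0.70 here and 0.68 in naive mice, and its interaction was not called with an estimated correlation (adjusted p = 0.52 with an estimated correlation). Of the brain endothelium list none of 23 was called (7 higher over the list alone), but 22 had positive values, with a median of 0.29 (adjusted p = 0.24 with an estimated correlation). Of the mitochondrially encoded list none of 13 was called (12 lower over the list alone), all 13 values were negative, and the median was -0.40 (adjusted p = 0.14 with an estimated correlation). The astrocyte list was also called with an estimated correlation, of which 1 of 15 was lower (4 over the list alone), Aqp4 (-0.38 ± 0.07, called in 17 of 26 alternatives). The other 20 lists called with the preset correlation were not called with an estimated one. Antigen presentation was one of these, with 4 of 16 lower (5 over the list alone), a mean of -0.59 and a median of 0.02 (adjusted p = 0.082 with an estimated correlation).

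In all, 40 genes differed between infected genotypes, 21 higher and 19 lower. The number was 15, 19 and 12 without WT infected replicates 1, 2 and 3, 17 and 18 without CCR2-DTR infected replicates 2 and 3, 75 without WT naive replicate 3, 164 when only these 6 libraries were fitted and 260 with DESeq2. The genotype effects in naive and infected mice, which share no library, correlated across genes with r = 0.295. The r was 0.193 without WT infected replicate 3, 0.0642 with no low-count filter, 0.0846 with DESeq2 and 0.614 with the stricter filter. Of all 19372 genes 72.0% had the same sign in both. Of 682 genes that differed in either, which were selected by these calls, 660 had the same sign in both. The 16 genes that differed in both, 6 higher and 10 lower, included Ccr3, Icam1, Bcl3, Tsc22d2, Idi1, Hmgcs1, Kcnj10 and Aqp4, where independent lists would share 0.275 and 0.396 genes.

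**Figure D4:**
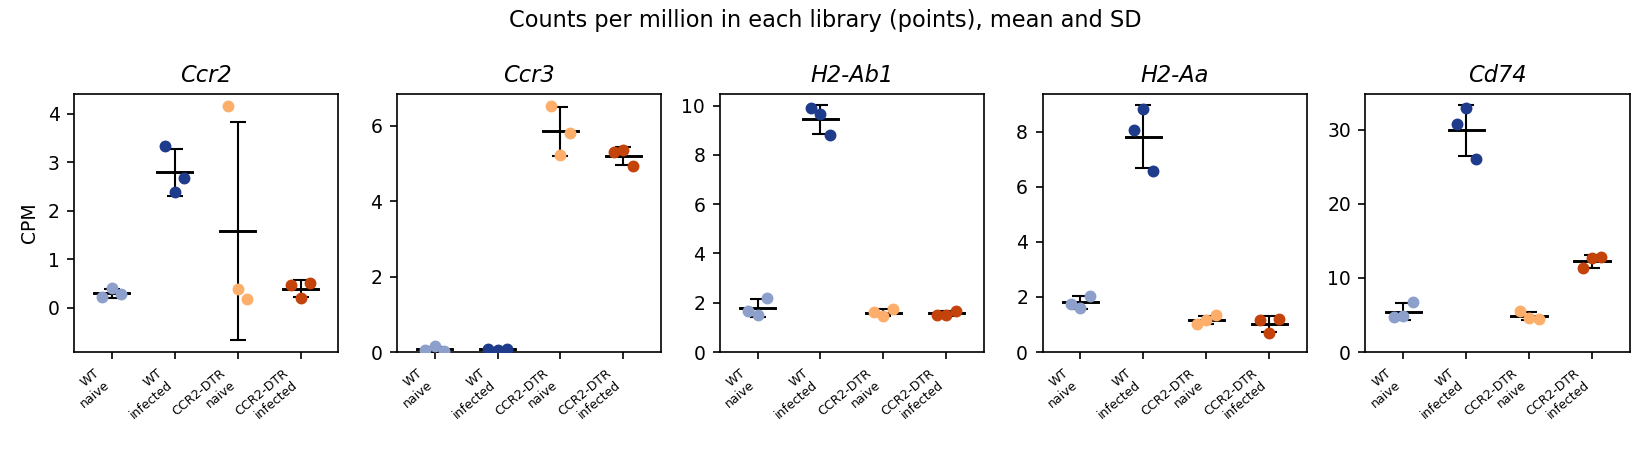
CPM (linear axes) of Ccr2, Ccr3, H2-Ab1, H2-Aa and Cd74 in each of the 12 libraries, with points for libraries, horizontal lines for group means and bars for SD (n = 3). H2-Ab1 lay at 9.45 ± 0.588 CPM in infected WT brains and at 1.57 ± 0.0884 CPM in infected CCR2-DTR brains.

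Whether the infection effect differed between the 2 genotypes was tested directly. The test passed for 3 genes, all of MHC class II. If only infected CCR2-DTR mice received toxin, an effect of toxin would be part of this difference. H2-Ab1 rose by 2.39 ± 0.13 in WT brains and had a log2 fold change of -0.03 ± 0.14 in CCR2-DTR brains, an interaction of -2.42 ± 0.20 (SE, edgeR adjusted p = 6.9e-05). The interaction was -2.31 ± 0.27 for H2-Aa (edgeR adjusted p = 0.0048) and -2.27 ± 0.30 for H2-Eb1 (edgeR adjusted p = 0.013). Cd40 (1.97 ± 0.32, edgeR adjusted p = 0.10) and Cd74 (-1.13 ± 0.19, edgeR adjusted p = 0.12) came next and did not pass. The H2-Ab1 call held under all 25 alternatives. The H2-Eb1 call was lost without WT naive replicate 2, WT infected replicate 1 or 2, or CCR2-DTR naive replicate 3, with log2 values between -2.26 and -2.19. H2-Aa and H2-Eb1 were also lost in both fits that addressed olfactory bulb content, with values from -2.61 to -2.30. Without CCR2-DTR naive replicate 2 the test passed for 27 genes. The preset correlation called 20 lists for the interaction and the estimated correlation 0 (6 at an unadjusted p under 0.05).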

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

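The tests of single explanations in this part, and the regrouped list counts with an estimated correlation, were chosen after the results they bear on had been seen. A difference between the infection effects of the 2 genotypes was found by the interaction test for H2-Ab1 (-2.42), H2-Aa (-2.31) and H2-Eb1 (-2.27). The camera test of the same contrast, with a preset correlation, picked 20 gene lists, none of which held with an estimated correlation. Their median interactions are given next, each followed by its range with 1 library left out. They were -0.62 for classical monocytes (-0.96 to -0.47), -0.14 for homeostatic microglia (-0.25 to -0.046), -0.26 for disease-associated microglia (-0.35 to -0.18), -0.18 for border-associated macrophages (-0.39 to -0.11), -0.47 for type 2 immunity (-0.59 to -0.13), -0.56 for interferon-stimulated genes (-0.80 to 0.13), -0.39 for antigen presentation (-0.58 to -0.18), -0.28 for complement (-0.37 to -0.17) and 0.047 for NF-kB and cytokines (0.006 to 0.36). They were -0.13 for reactive astrocytes (-0.32 to 0.018), 0.24 for brain endothelium (0.10 to 0.40), -0.17 for endothelial activation (-0.33 to -0.054), 0.12 for mural cells (0.00034 to 0.32), -0.22 for fibroblasts (-0.31 to -0.07), -0.063 for inhibitory neurons (-0.11 to 0.014), 0.10 for thalamus (0.048 to 0.16), -0.86 for olfactory bulb (-1.13 to -0.53), 0.52 for choroid plexus (0.22 to 0.72), -0.42 for proliferation (-0.64 to 0.12) and -0.65 for erythrocytes (-0.95 to -0.044). The medians of interferon-stimulated genes and proliferation turned positive without CCR2-DTR naive replicate 1, that of reactive astrocytes without WT naive replicate 3 and that of inhibitory neurons without CCR2-DTR naive replicate 2. That of erythrocytes was nearest 0 without CCR2-DTR naive replicate 3 and that of type 2 immunity without WT naive replicate 1.

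MHC class II genes rose with infection in WT and not detectably in CCR2-DTR brains. The suffix of the sample code is argued against, since the H2-Ab1 interaction was -2.50 in the CS167 libraries alone, of which there are 3 in infected CCR2-DTR mice and 2 in each other group. Fewer monocyte-derived cells in infected CCR2-DTR brains may account for it and stay open. The 14 classical monocyte genes other than Ccr2 had a median interaction of -0.61, 11 of them negative. A camera test with an estimated correlation gave p = 0.054, which missed the threshold. Between infected genotypes the whole list had a median of -0.09, with 7 values positive and 8 negative. There 1 of 15 was lower (4 over the list alone, camera adjusted p = 0.41 with an estimated correlation). Between naive genotypes the median was 0.26, with 12 of 15 positive, so the interaction also holds a naive difference.

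Ccr3 was higher in every CCR2-DTR library, at 4.92 to 6.52 CPM, than in any WT library. More eosinophils, which carry this receptor, may be a source and stay open. In naive mice the 4 other eosinophil genes had a median difference of -0.13, and each lay 4.58 (Ear2) to 14.5 (Epx) standard errors of the difference below Ccr3 (6.27). They lay under 0.4 CPM, and how they would rise with Ccr3 was not measured here, so they do not exclude it. The genotype itself, with its inserted construct, stays open.

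The calls of the 658 genes that differed by genotype in naive mice depended on the olfactory bulb score and on a correction for GC content and length. With the olfactory bulb score as a covariate, 652 of these genes outside the olfactory bulb list kept a median of 0.32 in the direction called (0.33 before) and 643 kept their sign, but 4 stayed called, because the median SE rose from 0.072 to 0.13. With the GC and length correction the median fell to 0.19 from 0.33, the median SE was 0.062, and 24 stayed called. Olfactory bulb tissue cannot be told apart from genotype because of these errors, nor can sequence composition, as the correction took away only part of the differences.

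The 10 groupings of 6 libraries are too few for a share under 0.05. The real gene counts and the highest of the other groupings were 2556 and 0 for infection in WT, 1337 and 0 for infection in CCR2-DTR, 658 and 2 for genotype in naive and 40 and 0 for genotype in infected, with 1 grouping as high in each. Counts of lists with the preset correlation did not set the real grouping apart. They were 23 and 25, 23 and 28, 19 and 22, and 22 and 22 in the same order, with 5, 7, 2 and 2 of 10 groupings as high. For the interaction, 15 of 100 regroupings of genotype within infection state gave at least 3 genes, the real grouping among them. The highest other count was 2112 and the next 10. The 2112 came from exchanging the genotype labels of all 6 infected libraries. That leaves both infection states apart by genotype, so it sums the 2 genotype effects and is not a regrouping by chance. All 15 kept the infected libraries apart by genotype and so hold the real difference between infected genotypes. Their number therefore cannot decide on chance, which is not excluded. Regroupings that mixed the infected libraries gave at most 2 genes. Of the same regroupings 34 of 100 gave at least 20 lists (highest other 26), so chance is not excluded. With an estimated correlation, run after these counts were seen, the real groupings gave 12, 11, 0 and 2 lists and every other grouping gave 0. The other groupings of 6 libraries mixed the 2 real groups, so a real difference adds to the spread within their groups. Their low gene counts and 0 lists are therefore no measure of what chance alone would give.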

How the results depend on the processing

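The CS167, GC and length, olfactory bulb and mitochondrial fits were chosen after the results had been seen. Over all alternatives, 3419 of 3959 values for the 154 named gene results kept their direction and side of the threshold, 523 fell below it, 9 passed it and 8 reversed. For the 107 list results the numbers were 2466 of 2758 kept, 276 lost and 16 reversed. Where the text gives no cause below, the cause was not tested.

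With the CS167 libraries only the result was 1634 genes for infection in WT, 364 genes for genotype in naive, 5 genes for interaction, r = 0.546 for the concordance of the infection effect. With the olfactory bulb score as a covariate the result was 296 genes for infection in CCR2-DTR, 6 genes for genotype in naive, 1 gene for interaction, r = 0.497 for the concordance of the infection effect, r = 0.432 for the concordance of the genotype effect. With both olfactory-rich CCR2-DTR naive libraries left out the result was 666 genes for infection in CCR2-DTR, 44 genes for genotype in naive, 87 genes for genotype in infected, r = 0.550 for the concordance of the infection effect. With DESeq2 the result was 1709 genes for genotype in naive, 260 genes for genotype in infected, 7 genes for interaction, r = 0.196 for the concordance of the infection effect, r = 0.0846 for the concordance of the genotype effect. With the replicate block the result was 1414 genes for genotype in naive, 89 genes for genotype in infected. With the code suffix as a covariate the result was 1031 genes for genotype in naive. With the GC and length correction the result was 25 genes for genotype in naive. With only the compared groups fitted the result was 9 genes for genotype in naive, 164 genes for genotype in infected. With no low-count filter the result was 73 genes for genotype in infected, r = 0.148 for the concordance of the infection effect, r = 0.0642 for the concordance of the genotype effect. With limma voom with quality weights the result was 174 genes for genotype in infected, 12 lists for interaction. With an estimated correlation the result was 12 lists for infection in WT, 11 lists for infection in CCR2-DTR, 0 lists for genotype in naive, 2 lists for genotype in infected, 0 lists for interaction. With the stricter filter the result was r = 0.858 for the concordance of the infection effect, r = 0.614 for the concordance of the genotype effect. The filter settings and DESeq2 take in other sets of genes, and no other cause of their concordances was tested.

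The direction of a list is that of camera, so its median may keep its sign. Reversed with the olfactory bulb score as a covariate: Eomes (infection in CCR2-DTR) at 0.052, Cpa6 (infection in CCR2-DTR) at 0.046, Lgr5 (infection in CCR2-DTR) at 0.061, Otop2 (infection in CCR2-DTR) at 0.068, Eomes (genotype in naive) at -0.18, Shisa3 (genotype in naive) at -0.39, Ppm1j (genotype in naive) at -0.19, Sp8 (genotype in naive) at -0.14, the brain endothelium list (infection in CCR2-DTR) at -0.072, the choroid plexus list (infection in CCR2-DTR) at 0.034, the interferon-stimulated genes list (genotype in naive) at -0.24, the antigen presentation list (genotype in naive) at 0.0079, the cholesterol synthesis list (genotype in naive) at 0.087, the interferon-stimulated genes list (interaction) at 0.28, the brain endothelium list (interaction) at -0.070, the mural cells list (interaction) at -0.080, the erythrocytes list (interaction) at -0.13. Reversed with the stricter filter: the type 2 immunity list (genotype in infected) at -0.059, the type 2 immunity list (interaction) at 0.026. Reversed with both olfactory-rich CCR2-DTR naive libraries left out: the interferon-stimulated genes list (interaction) at 0.15, the mural cells list (interaction) at -0.045, the proliferation list (interaction) at 0.087, the erythrocytes list (interaction) at 0.016. Reversed without CCR2-DTR naive replicate 1: the interferon-stimulated genes list (interaction) at 0.13. Over all libraries left out in turn its values were between -0.80 and 0.13.

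Leaving out 1 library gave 1281 to 3035 genes for infection in WT, 749 to 1553 genes for infection in CCR2-DTR, 21 to 985 genes for genotype in naive, 12 to 75 genes for genotype in infected, 2 to 27 genes for interaction, 19 to 25 lists for infection in WT, 21 to 25 lists for infection in CCR2-DTR, 15 to 22 lists for genotype in naive, 20 to 24 lists for genotype in infected, 15 to 21 lists for interaction, 0.557 to 0.634 for the concordance of the infection effect, 0.193 to 0.314 for the concordance of the genotype effect. The labels number replicates 1 to 3 in each group. The numbers were not taken to pair the samples, since the deviations of same-numbered libraries correlated above 0.1 in only 5 of 18 pairs (range -0.046 to 0.161). As a hint of pairing, 14 of the 18 were above 0, and 7 of 12 libraries correlated best with a library of their own number, against 4 by chance. With the replicate block 3255, 1794, 1414, 89 and 3 genes and 22, 23, 19, 23 and 21 lists were called for the 5 contrasts in the order of the methods, and the concordances were 0.629 and 0.294. With other settings the split of changed genes moved by over 10 points for infection in WT with upper-quartile scaling (1818 higher, 656 lower), only the compared groups (1443, 568), the CS167 libraries (1204, 430) and the GC and length correction (1430, 1398). For infection in CCR2-DTR it did so with that correction (1107, 729), the replicate block (1266, 528), the olfactory bulb score (290, 6) and without both olfactory-rich libraries (640, 26), and without CCR2-DTR infected replicate 1 (898, 88) or 3 (684, 65). The low-count genes Tnf, Il1b and Ccr2 may be limited by depth, which was not tested. Ccr2 also varied between the naive CCR2-DTR libraries, at 227, 23 and 10 counts in replicates 1, 2 and 3.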

Other observations

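The clock gene Arntl fell in WT (-0.57 ± 0.08, SE) and CCR2-DTR brains (-0.37 ± 0.08), and its repressor Bhlhe41 rose (0.44 ± 0.05 and 0.22 ± 0.05). In the circadian list 3 of 15 genes were higher and 3 lower in WT brains, and the list was not called in either genotype. Of the heat shock list 5 of 17 fell and 1 rose in WT brains, as in the chaperone genes Hsph1 (-0.52 ± 0.08) and Hspa8 (-0.48 ± 0.11, adjusted p of the list = 0.56 with an estimated correlation). The B cell receptor gene Cd79b rose by 2.27 ± 0.33 in WT brains, 1 of 3 of 11 tested lymphocyte genes that rose.

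The genes of the following sentences were chosen after their values had been seen. Naive CCR2-DTR replicate 1 stood apart in some of them. Ifit1, an interferon-stimulated gene, was at 19.2 CPM there and 4.06 and 4.75 CPM in the other 2 libraries of its group. Ttr, a choroid plexus gene, was at 221.3 CPM there against 435.3 and 534.0 CPM. The neutrophil gene S100a8 was highest in replicate 2 of both CCR2-DTR groups, at 5.64 CPM in naive and 8.32 CPM in infected mice. The mitochondrially encoded share was 16.8% ± 2.12 in infected WT and 13.1% ± 0.504 in infected CCR2-DTR libraries (SD, n = 3).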
